A study of Mus musculus with 6 samples.

How the data were processed

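RNA of Pax7-nGFP+ limb cells was measured on 6 single-colour Affymetrix arrays, 3 from E12.5 and 3 from E17.5 mouse embryos on a mixed C57BL/6 and DBA2 background. Per the labels' protocols, limbs were digested with trypsin, the cells were filtered and GFP-positive cells were sorted, total RNA was isolated with a column kit, and 100 ng of it was amplified in a two-cycle 3' protocol before labelling with biotin. Amplification from the 3' end makes the signal depend on probe position and RNA integrity.

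The deposited values are log2 signals per probe set made by the authors with GCRMA, per the submitters' processing notes, with its version not given in the sources used here. GCRMA corrects background with probe sequence, normalizes between arrays and summarises probes. It compresses probe sets without specific signal into a dense low range, here mostly under 4, so a difference against that range depends on the background model. The array values ran from 0.96 to 15.94. The depth of an array is its signal over background: 42.8% of genes (7777 of 18182) had a mean under 4.

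Probe sets were named through the platform annotation supplied with the data, and symbols were updated by entrez ID to the RefSeq gene list of assembly GRCm38.p6, used for names only. Of 44994 probe sets 34909 had 1 symbol (34705 matched by entrez ID), 931 had several and were left out, and 9154 were not named here. Each of the 18182 genes was represented by the probe set with the highest mean over all 6 arrays. Of 1945 called genes with several probe sets, 6 had one called in the opposite direction.

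Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with no filter and no further normalization, and p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05 and a fold threshold of 2 for the second pair of counts. The lists were tested with camera, with the correlation between genes preset to 0.01 and adjustment over the 39 lists. They were written from textbook knowledge before the data were examined, hold 1132 entries of which 1065 were measured (5 through an older symbol), and share 41 genes among them. Of these lists 12 hold markers of other cell types. Named genes were chosen by a rule also fixed before the data were examined. It takes the 6 largest rises and 6 largest falls among called genes whose ages do not overlap and whose higher mean is at least 6, then 14 genes named whatever their result, then up to 3 risen and 3 fallen members per list, or 2 members of a list without calls. It gave 178 genes, and 0 clone-type symbols were skipped. Another 16 genes were named after their values were seen, in the closing part only. Some further genes outside the rule are named to describe the arrays, connective tissue genes or the overlap of lists, and are not in these counts. They are Xist, Eif2s3y, Postn, Fmod, Tnc, Col12a1, Prrx1, Prrx2, Col1a2 and Col3a1.

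The labels describe the replicates as biological. E17.5 replicates A and B differed by far less than other arrays of one age, so each count was also taken with their mean as 1 sample. The planned comparison of 3' and 5' control probe sets was not run, because no such probe sets are among the rows analysed here, and RNA integrity is therefore not assessed.

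The fits were tested on simulated data with the real genes' means and spreads (20 runs, 18182 genes, 200 changed genes per run, E17.5 against E12.5). Of genes changed 1.5-fold 37.8% were called with the right sign, of those changed 2-fold 57.8%, 4-fold 85.4% and 8-fold 93.6%, and 4.98% of calls fell on unchanged genes. The 6 arrays were drawn independently here, with a spread pooled over both ages. These shares therefore do not hold for the real fit if E17.5 A and B are near copies. They also apply to 200 changed genes per run only. The real fit called 3080 genes, and with more calls the Benjamini-Hochberg adjustment passes larger unadjusted p-values. Camera called a list of 30 genes shifted 2-fold in 20 of 20 runs, and 1 unshifted list over all runs, but the simulated genes were independent of each other. With no change at all, 5.46% of genes had an unadjusted p under 0.05. With 2 arrays of one age simulated as near copies this rose to 10.3%, and with the copies averaged it was 5.69%. The median number of genes called at an adjusted p under 0.05 was 0 in each of these cases. Since no gene was changed there, this does not give the number of false calls in the real fit.

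The alternatives were other variance priors, array weights, other choices of probe set, filters on mean signal at 4 and 6, a floor at 4, centring on bright genes, a further quantile normalization, the replicate letter as a block, a threshold of 0.01, other list tests, and leaving out each array in turn. The averaging of E17.5 A and B and the lists without shared members were added after the data were seen. Figures were drawn with matplotlib 3.10.9.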

Results

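Gene expression was profiled in limb cells carrying nuclear GFP under the control of Pax7, the paired-box transcription factor that marks skeletal muscle stem and progenitor cells. The cells were isolated by fluorescence-activated sorting from transgenic mouse embryos at embryonic stage E12.5 (limb buds) and from fetuses at E17.5, and each age was represented by 3 arrays that the labels call biological replicates A, B and C. The design holds 1 comparison, E17.5 against E12.5, and it asks how the transcriptome of Pax7-expressing limb cells differs between the embryonic and the fetal phase of muscle formation. Values are log2 signals after GCRMA, means are given ± SD with n = 3 arrays per age, and each difference is E17.5 minus E12.5 on the log2 scale with the standard error (SE) and Benjamini-Hochberg adjusted p of limma. The array medians lay between 3.38 and 3.47, and between 33.7% and 34.8% of probe sets on an array had a value of at least 6. The number of arrays limits the precision.

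The arrays separated first by age, along a principal component that held 77.1% of the variance over 18182 genes, and a second component held 11.4%. E17.5 replicates A and B were closer to each other than any other pair of one age. The SD of their difference was 0.152 over genes with a mean of at least 6, against 0.412 to 0.551 in the 5 other same-age pairs, and 3 genes differed between them by at least 1, against 276 to 596 genes. They held exactly the same value in 8939 probe sets, but so did E12.5 A and C in 8666, against 417 to 831 in the 4 other same-age pairs and up to 3419 across ages. Most of these probe sets had a mean under 4 (8189 and 8337), and with a mean of at least 6 they were 516 for E17.5 A and B and 221 for E12.5 A and C. The sex-linked transcripts Xist and Eif2s3y stood at 12.61 and 10.21 in replicate A and at 12.62 and 10.20 in replicate B. Because these 2 arrays may not be independent samples, counts are also given with E17.5 A and B averaged and counted as 1 sample (3 arrays against 2), an alternative chosen after the data were seen and called the averaged count below. Where leaving out 1 array moved a list's count by over 1.5 times, the range of the rises and of the falls over those 6 fits is given as well. Fits with array weights gave E17.5 A and B weights of 4.98 and 3.24, against 0.140 for E17.5 C. Calls gained with array weights therefore lean on 2 arrays that may not be independent.

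At E17.5 the largest rise among genes named by a fixed rule was that of Dpt, the matrix protein dermatopontin, from 2.10 ± 0.44 to 11.14 ± 0.09 (difference 9.04, SE 0.27, adjusted p = 2.65e-05). It was followed by Fosb, an AP-1 subunit (8.08), Ccn3, a matricellular protein (7.27), Asb5 (6.89), Itga7, the laminin-binding integrin alpha 7 of muscle (6.84), and the chemokine gene Cxcl1 (6.44). The largest fall was that of Hbb-y, an embryonic beta-like globin, from 14.08 ± 0.96 to 3.67 ± 0.69 (difference -10.41, SE 0.54, adjusted p = 0.000105). It was followed by the tight junction gene Cldn9 (-6.77), the LIM homeobox gene Lhx9 (-6.24), Sulf2, an extracellular heparan sulfate sulfatase (-5.95), Shisa3 (-5.92) and the ephrin receptor gene Epha4 (-5.73). The rule took these 12 genes only among called genes whose ages did not overlap. Over all 18182 genes, 5708 (31.4%, against 10% by chance for 6 independent arrays) had all 3 arrays of one age above all 3 of the other. The share by chance is higher if E17.5 A and B are not independent.

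In all, 1493 genes were higher and 1587 lower at E17.5, 1032 and 924 of them by at least 2-fold. The averaged counts were 1021 higher and 825 lower, and 865 and 649 by at least 2-fold. Without E17.5 replicate A 836 genes were lower, without E17.5 replicate B 970 were higher and 771 lower, and without E12.5 replicate C 1052 were lower. Low signals carry part of these differences, since 42.8% of genes had a mean under 4, where GCRMA values hold little specific signal. With every value under 4 raised to 4, the difference of Dpt was 7.14 and that of Hbb-y was -9.93. The order of the named genes below them changed. Cd44 (6.40) passed Fosb (6.34), Ccn3 was at 5.83, and Cxcl1 (5.66) passed Asb5 (5.61) and Itga7 (5.06). Among the falls Sulf2 (-5.95) passed Cldn9 (-5.82), and Hoxd13 (-5.46), Epha4 (-5.08) and Shisa3 (-4.92) passed Lhx9 (-4.77). The choice of probe set mattered too: with the mean of a gene's probe sets 62 of 189 called named genes differed by over 1.5 times in size, such as Cldn9 (-3.56) and Lhx9 (-3.61), and without probe sets that can match several transcripts 10 did, such as Hbb-y (-6.81), Ifi35 (1.38), Dmp1 (2.18) and Jarid2 (-2.09). The fall of Sulf2 rested on a probe set that can match several transcripts, and among its other probe sets the brightest differed by -0.13 (adjusted p = 0.901).

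Among the regulators of muscle progenitors, Pax7 itself rose slightly, from 11.46 ± 0.28 to 12.37 ± 0.15 (difference 0.91, SE 0.16, adjusted p = 0.0105). Its paralogue Pax3, which acts in embryonic myogenesis, fell from 7.94 ± 1.0 to 5.38 ± 0.20 (-2.56, SE 0.49, adjusted p = 0.0142; 0.0527 without E12.5 replicate C). Tcf15, a basic helix-loop-helix factor of somites, fell by 3.30 and the transcription cofactor gene Dach1 fell by 2.67. Of the 19 measured members of this group, 1 rose, 9 fell and 9 were not called (2 and 9 adjusted over the list alone, averaged count 1 and 8, without 1 array 1 to 2 and 7 to 10). The group was lower by camera (adjusted p = 0.00137; adjusted p = 0.178 with an estimated correlation; adjusted p = 0.168 over genes with a mean of at least 6). The determination genes Myf5 and Myod1 were not called, at 0.90 (SE 0.29, adjusted p = 0.084) and 0.15 (SE 0.13, adjusted p = 0.574). Myf5 was called without E12.5 replicate A (1.17, adjusted p = 0.0239) and in fits that left out dim genes or weighted the arrays.

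Myog, the transcription factor gene of terminal muscle differentiation, rose from 11.20 ± 0.75 to 13.06 ± 0.07 (difference 1.86, SE 0.35, adjusted p = 0.0128). Jsrp1, a component of the junction between sarcoplasmic reticulum and surface membrane, rose by 4.51, Stac3, needed for excitation-contraction coupling, by 4.25, and the small heat shock gene Hspb2 by 3.13. Of the 27 measured differentiation regulators, 14 rose, 1 fell and 12 were not called (16 and 1 adjusted over the list alone, averaged count 14 and 1). Camera called the list higher (adjusted p = 1.9e-08; adjusted p = 0.123 with an estimated correlation). Of 44 sarcomere genes 9 rose, 5 fell and 30 were not called (11 and 5 adjusted over the list alone, averaged count 8 and 1, without 1 array 8 to 12 and 1 to 5). Among the rises were Tnnt2 (3.57), Tnni2 (3.12) and the creatine kinase gene Ckm (2.80), and among the falls the slow myosin gene Myh7 (-2.33). With the floor at 4, Ckm was at 1.27 and Myh7 at -1.13, since 1 age lay near the background range. That list had a median difference of 0.09 and was not called by camera (adjusted p = 0.0649). It was called higher without E12.5 replicate B (median 0.22, adjusted p = 0.00513) or E17.5 replicate C (0.06, adjusted p = 0.0306). It was also called higher over its members with a mean of at least 4 (0.56, adjusted p = 0.00849) or over all such genes (adjusted p = 0.0199). Other fits that called it higher were those with the floor at 4 (adjusted p = 0.0355), with arrays centred on bright genes (adjusted p = 0.0366) and with array weights (adjusted p = 0.011).

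**Figure D1:**
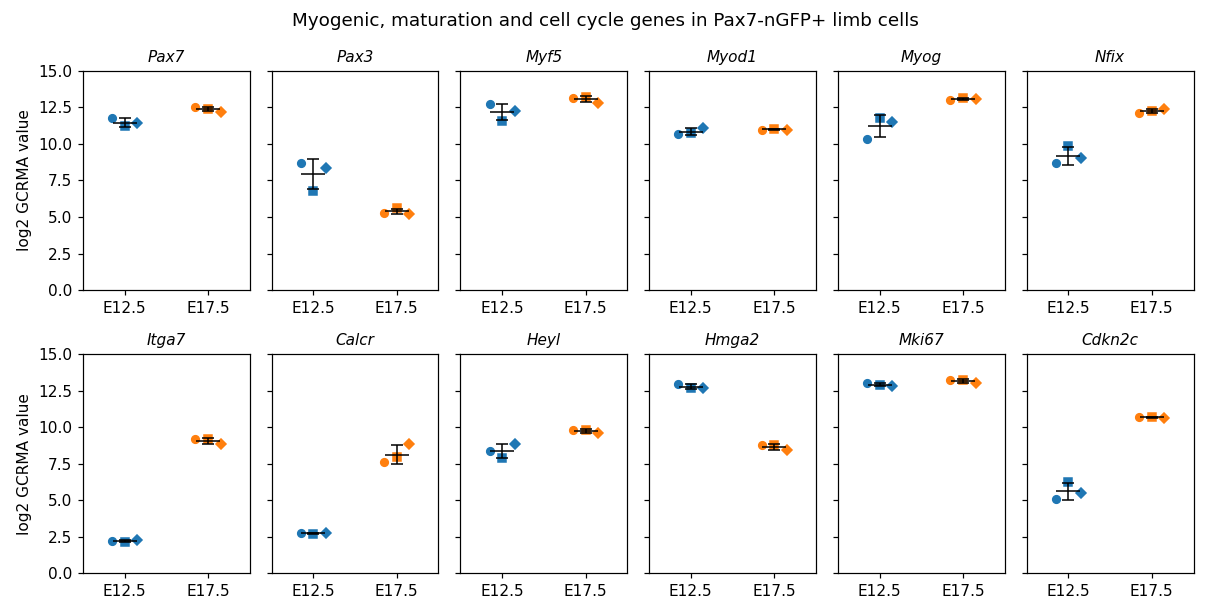
Log2 GCRMA values of 12 genes on each array (circle, square and diamond for replicates A, B and C; blue E12.5, orange E17.5), with the mean as a black dash and the SD as bars, n = 3 arrays per age. Nfix, Itga7, Calcr and Cdkn2c stood higher and Hmga2 and Pax3 lower at E17.5, whereas Myod1 and Mki67 differed by 0.15 and 0.24 and were not called.

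Genes known from fetal myoblasts and from adult satellite cells, the muscle stem cells, were higher at E17.5. Nfix, a nuclear factor I gene that drives the fetal myogenic program, rose from 9.20 ± 0.61 to 12.27 ± 0.14 (difference 3.07, SE 0.29, adjusted p = 0.000832). Prkcq, which encodes protein kinase C theta, rose by 5.52. Of the 12 fetal myoblast markers 10 rose, 1 fell (Eno3, -1.53) and 1 was not called, with the same counts adjusted over the list alone and an averaged count of 9 and 1. The list was higher by camera (adjusted p = 7.2e-09; adjusted p = 0.0572 with an estimated correlation).

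Calcr, the calcitonin receptor gene of quiescent satellite cells, rose from 2.75 ± 0.03 to 8.13 ± 0.64 (difference 5.38, SE 0.35, adjusted p = 0.000213, and 4.13 with the floor at 4). Cd34 rose by 4.91 and Spry1, a feedback inhibitor of receptor tyrosine kinases, by 0.94 (SE 0.17, adjusted p = 0.0117). Of 34 measured satellite cell and quiescence markers, 17 rose, 1 fell (Nfatc4, -3.39) and 16 were not called (21 and 2 adjusted over the list alone, averaged count 16 and 1, without 1 array 15 to 18 and 1 to 2). The list was higher by camera (adjusted p = 9.64e-09), also with an estimated correlation (adjusted p = 0.0436). Itga7 belongs to both of these lists and to the integrin list.

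Cell cycle inhibitors rose while proliferation genes as groups were not called. Mki67, a marker of cycling cells, was at 12.91 ± 0.09 and 13.16 ± 0.14 (difference 0.24, SE 0.10, adjusted p = 0.189). It was called with array weights, which lean on E17.5 A and B (0.39, adjusted p = 0.000592). Among 22 measured inhibitors 15 rose, none fell and 7 were not called (17 and 0 adjusted over the list alone, averaged count 11 and 0). The list was higher by camera (adjusted p = 3.23e-09), also with an estimated correlation (adjusted p = 0.0436). Cdkn2c, which encodes the CDK4 and CDK6 inhibitor p18, rose from 5.63 ± 0.57 to 10.67 ± 0.04 (difference 5.05, SE 0.29, adjusted p = 0.000136). The stress-responsive genes Gadd45a and Gadd45b rose by 2.97 and 2.69. Cdkn1c, the p57 gene, differed by 0.46 (SE 0.11, adjusted p = 0.0294). That call was lost in the averaged fit (adjusted p = 0.11), with the replicate block or the floor, and without any one of E12.5 B, E12.5 C, E17.5 A and E17.5 B (adjusted p 0.0531 to 0.119).

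Of 44 G1/S and DNA replication genes 4 rose, 5 fell and 35 were not called (4 and 7 adjusted over the list alone, averaged count 3 and 2, without 1 array 2 to 3 and 2 to 7). The activating E2F gene E2f2 rose by 1.96 and the cyclin D1 gene Ccnd1 fell by 0.89. Of 49 G2/M and mitosis genes 3 rose, 5 fell and 41 were not called (2 and 5 adjusted over the list alone, averaged count 0 and 2, without 1 array 0 to 2 and 2 to 9). The 9 falls came without E12.5 replicate A. The cyclin F gene Ccnf fell by 1.98. The camera tests of these 2 lists gave adjusted p = 0.254 and adjusted p = 0.367, and their median differences were -0.11 and -0.10 (-0.16 to -0.039 and -0.12 to -0.057 without 1 array).

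Extracellular matrix genes and their receptors were higher at E17.5. Col15a1, a basement membrane collagen gene, rose from 2.96 ± 0.49 to 9.38 ± 0.59 (difference 6.42, SE 0.39, adjusted p = 0.00018, and 5.38 with the floor at 4). The proteoglycan gene Bgn rose from 6.69 ± 0.54 to 11.64 ± 0.45 (4.95, SE 0.33, adjusted p = 0.000227), while Col25a1, a membrane collagen gene, fell by 3.86. Of 49 measured matrix genes 26 rose, 2 fell and 21 were not called (30 and 3 adjusted over the list alone, averaged count 21 and 2, without 1 array 20 to 31 and 2 to 4). The 4 falls came without E12.5 replicate A. By camera the list was higher (adjusted p = 6.48e-11; adjusted p = 0.154 with an estimated correlation). Of 16 fibroblast genes 4 rose and 5 fell, and of 10 tenocyte genes 4 rose, but these lists share members with the matrix list. Of the risen fibroblast genes, Col1a1 and Postn are in it and Dpt and Ogn are not. Of the tenocyte genes, Fmod, Thbs4, Tnc, Col12a1 and Col14a1 are in it. Without shared members the tenocyte median was -0.20 (camera adjusted p = 0.971). Fibroblast and cartilage genes also differed between arrays of one age, and their median was 1.4 higher in E12.5 replicate B than in the mean of A and C.

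Of 38 integrins and other matrix receptors 15 rose, 2 fell and 21 were not called (17 and 2 adjusted over the list alone, averaged count 13 and 2). The list was higher by camera (adjusted p = 7.85e-07), also with an estimated correlation (adjusted p = 0.0466). The hyaluronan receptor gene Cd44 rose by 6.40 and Itga8 by 4.33, whereas Itga9 fell by 3.47 and Itga4 fell by 2.79. Among 28 matrix proteases and inhibitors 9 rose, 5 fell and 14 were not called (10 and 6 adjusted over the list alone, averaged count 6 and 2, without 1 array 5 to 8 and 2 to 5). Adamts1 and Adamts5 rose by 2.59 and 2.48, and Plat and the crosslinking enzyme gene Lox were lower (-1.89 and -1.73). That list had a median difference of -0.06 (-0.029 to 0.042 without 1 array), a mean of 0.30 and no camera call (adjusted p = 0.47).

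Signalling pathways were divided. In the Notch pathway the receptor gene Notch1 rose from 10.22 ± 0.10 to 12.27 ± 0.06 (difference 2.05, SE 0.09, adjusted p = 7.63e-05). Dtx4 rose by 2.56 and the target gene Heyl by 1.36 (SE 0.25, adjusted p = 0.0113; 0.0533 with the mean of its 3 probe sets). Other targets fell: Nrarp fell by 2.11 and Hes1 fell by 0.71 (SE 0.14, adjusted p = 0.0137; 0.0628 in the averaged fit, 0.0624 without E17.5 replicate A and 0.0655 without E17.5 replicate B). Of 31 members 6 rose, 6 fell and 19 were not called (8 and 9 adjusted over the list alone, averaged count 4 and 3, without 1 array 4 to 6 and 2 to 6), with a median of -0.01 (-0.043 to 0.015 without 1 array), a mean of 0.07 and no camera call (adjusted p = 0.828). Of 24 FGF receptors and feedback targets 5 rose, including Fgfr4 (1.64), 4 fell and 15 were not called (7 and 4 adjusted over the list alone, averaged count 3 and 2, without 1 array 2 to 7 and 2 to 4, camera adjusted p = 0.652).

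Bmp6 rose from 2.5 ± 0.10 to 8.01 ± 0.06 (difference 5.51, SE 0.21, adjusted p = 4.64e-05, and 4.01 with the floor at 4). Fst, an activin and BMP antagonist, fell by 4.76, the receptor gene Bmpr1b fell by 2.29 and the inhibitory Smad gene Smad6 fell by 2.21. Of 44 BMP and TGF-beta genes 8 rose, 12 fell and 24 were not called (9 and 12 adjusted over the list alone, averaged count 6 and 9), with a median near 0, a mean of -0.17 and no camera call (adjusted p = 0.362). In the Wnt pathway Lgr5, an R-spondin receptor gene, fell by 4.39, the ligand gene Wnt5a fell by 3.91 and the feedback gene Nkd2 fell by 3.62. Of 46 Wnt genes 4 rose, 12 fell and 30 were not called (4 and 14 adjusted over the list alone, averaged count 1 and 10, without 1 array 0 to 5 and 9 to 13). No member rose without E17.5 replicate A. The Wnt list had a median difference of -0.13 and a mean of -0.79, and 16 members had a mean signal under 4. The list was lower by camera (adjusted p = 0.00472; adjusted p = 0.123 with an estimated correlation; adjusted p = 0.0536 without E17.5 replicate C). That call was also lost with a correlation of 0.05 (adjusted p = 0.0769), with array weights (adjusted p = 0.203) and over genes with a mean of at least 6 (adjusted p = 0.338).

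Axon guidance genes were lower as a group. Besides Epha4, the semaphorin coreceptor gene Nrp2 fell by 4.19 and Slit2 fell by 3.93, whereas the netrin genes Ntn4 and Ntn1 rose by 5.84 and 3.72 (Ntn1 2.47 with the floor at 4). Of 44 members 6 rose, 17 fell and 21 were not called (7 and 20 adjusted over the list alone, averaged count 5 and 12). The list's median difference of -0.685 ran from -0.78 without E12.5 replicate A to -0.39 without E12.5 replicate B (camera adjusted p = 0.0314 without B). The camera call (adjusted p = 0.001) was lost with an estimated correlation (adjusted p = 0.416), with array weights (adjusted p = 0.379) and over genes with a mean of at least 6 (adjusted p = 0.127).

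Hmga2, a chromatin protein gene of embryonic cells, fell from 12.76 ± 0.18 to 8.64 ± 0.19 (difference -4.12, SE 0.14, adjusted p = 3.68e-05), the RNA-binding protein gene Trim71 fell by 4.26 and Igf2bp1 fell by 2.65. Lin28b was near the lower end of the scale at both ages (3.40 ± 0.14 and 3.48 ± 0.24, adjusted p = 0.87). Of the 10 measured members of the Lin28, Hmga and Igf2bp group none rose, 6 fell and 4 were not called (0 and 6 adjusted over the list alone, averaged count 0 and 5). The group was lower by camera (adjusted p = 6.3e-05; adjusted p = 0.193 with an estimated correlation).

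Among 38 measured Hox and limb patterning genes none rose, 8 fell and 30 were not called (0 and 8 adjusted over the list alone, averaged count 0 and 5, without 1 array 0 and 5 to 8). Hoxd13, a distal limb Hox gene, fell by 5.46 and the hindlimb gene Pitx1 fell by 3.95. The list's median difference of -0.33 ran from -0.46 without E12.5 replicate C to -0.042 without E12.5 replicate B (camera adjusted p = 0.0333 without B). The camera call (adjusted p = 0.00417) was lost with an estimated correlation (adjusted p = 0.486). It was also lost with a correlation of 0.05 (adjusted p = 0.062), with array weights (adjusted p = 0.285) and over genes with a mean of at least 4 (adjusted p = 0.056) or 6 (adjusted p = 0.27). Limb mesenchyme genes of the fibroblast list also differed between arrays of one age, as given below. Of 26 imprinted growth genes 13 rose, 1 fell (Nnat, -3.45) and 12 were not called (16 and 2 adjusted over the list alone, averaged count 7 and 1, without 1 array 6 to 14 and 1 to 2). The 6 rises came without E17.5 replicate B. Dlk1 rose by 5.64, Mirg by 3.48 and Rian by 2.81. The list was higher by camera (adjusted p = 6.05e-06; adjusted p = 0.0572 with an estimated correlation). Of 37 chromatin and DNA methylation regulators 3 rose, 8 fell and 26 were not called (3 and 10 adjusted over the list alone, averaged count 1 and 4, without 1 array 1 to 4 and 4 to 7, camera adjusted p = 0.191). Hdac11 rose by 2.12, while Jarid2 fell by 1.36 and the DNA methyltransferase gene Dnmt3b fell by 1.27.

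In metabolism, glycolysis genes were lower at E17.5. Pgam2, the muscle phosphoglycerate mutase gene, fell from 9.05 ± 0.45 to 4.23 ± 0.29 (difference -4.83, SE 0.30, adjusted p = 0.000189) and the lactate dehydrogenase gene Ldhb fell by 2.96. Of 24 members none rose, 9 fell and 15 were not called (1 and 10 adjusted over the list alone, averaged count 0 and 8, without 1 array 0 to 2 and 8 to 11). The 2 rises came without E12.5 replicate B. The list was lower by camera (adjusted p = 6.36e-05; adjusted p = 0.128 with an estimated correlation). Ribosome biogenesis genes and MYC targets were lower too: none of 39 rose, 10 fell and 29 were not called (0 and 16 adjusted over the list alone, averaged count 0 and 6, without 1 array 0 to 1 and 6 to 14). Mycn fell by 2.25, Rrp1b fell by 1.5 and Cad, an enzyme gene of pyrimidine synthesis, fell by 1.42. That list was lower by camera (adjusted p = 5.58e-08; adjusted p = 0.123 with an estimated correlation).

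Among 31 fatty acid genes 9 rose, 3 fell and 19 were not called (12 and 3 adjusted over the list alone, averaged count 7 and 1, without 1 array 7 to 11 and 1 to 3). The fatty acid binding protein gene Fabp4 rose by 4.26 and Pdk4, which restrains glucose oxidation, by 4.13. Camera called these genes higher (adjusted p = 0.00472; adjusted p = 0.128 with an estimated correlation). The call was also lost with a correlation of 0.05 (adjusted p = 0.0582) and over genes with a mean of at least 6 (adjusted p = 0.0611). Oxidative phosphorylation genes were not called as a group (adjusted p = 0.999). Of 63 members 1 rose, Sdhd by 0.49 (SE 0.13, adjusted p = 0.0442), none fell and 62 were not called, and 0 passed when adjusted over the list alone. These counts rested on single arrays: without E17.5 replicate C 10 members were lower and 1 higher, without E12.5 replicate A 2 were lower, and 1 was with the floor at 4. The call of Sdhd was lost in the averaged fit and without any one of the E12.5 arrays, E17.5 A or E17.5 B.

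Immediate early and dissociation-responsive genes were much higher at E17.5. Besides Fosb, the stress factor gene Atf3 rose from 2.91 ± 0.22 to 8.85 ± 0.38 (difference 5.95, SE 0.28, adjusted p = 7.99e-05, and 4.85 with the floor at 4). The inducible heat shock gene Hspa1a rose by 5.73. Of 30 members 22 rose, 1 fell and 7 were not called (26 and 1 adjusted over the list alone, averaged count 19 and 1, without 1 array 18 to 24 and 0 to 1), with a median difference of 2.77. The list was higher by camera (adjusted p = 2.75e-15; adjusted p = 0.128 with an estimated correlation). The labels give the same trypsin digestion for both ages.

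Of 27 complement and cytokine genes 7 rose, 2 fell and 18 were not called (8 and 2 adjusted over the list alone, averaged count 7 and 0, without 1 array 7 and 0 to 1). Socs3, a feedback inhibitor of cytokine receptors, rose by 4.52 and Tnfrsf12a by 4.05. The list's median difference was only 0.03 and its mean 0.76, and 12 members had a mean signal under 4. By camera the list was higher (adjusted p = 0.00262; adjusted p = 0.123 with an estimated correlation). Of 29 antigen presentation and interferon genes 7 rose, 2 fell and 20 were not called (8 and 2 adjusted over the list alone, averaged count 8 and 1, without 1 array 5 to 8 and 1 to 3). Irf1 and Ifi35 rose by 4.27 and 3.60, and Ifitm1 fell by 2.82. The interferon list had a median difference of 0.12 and a mean of 0.66, and 16 members had a mean signal under 4. That list was higher by camera (adjusted p = 0.00811; adjusted p = 0.426 with an estimated correlation; adjusted p = 0.0723 with a correlation of 0.05).

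**Figure D2:**
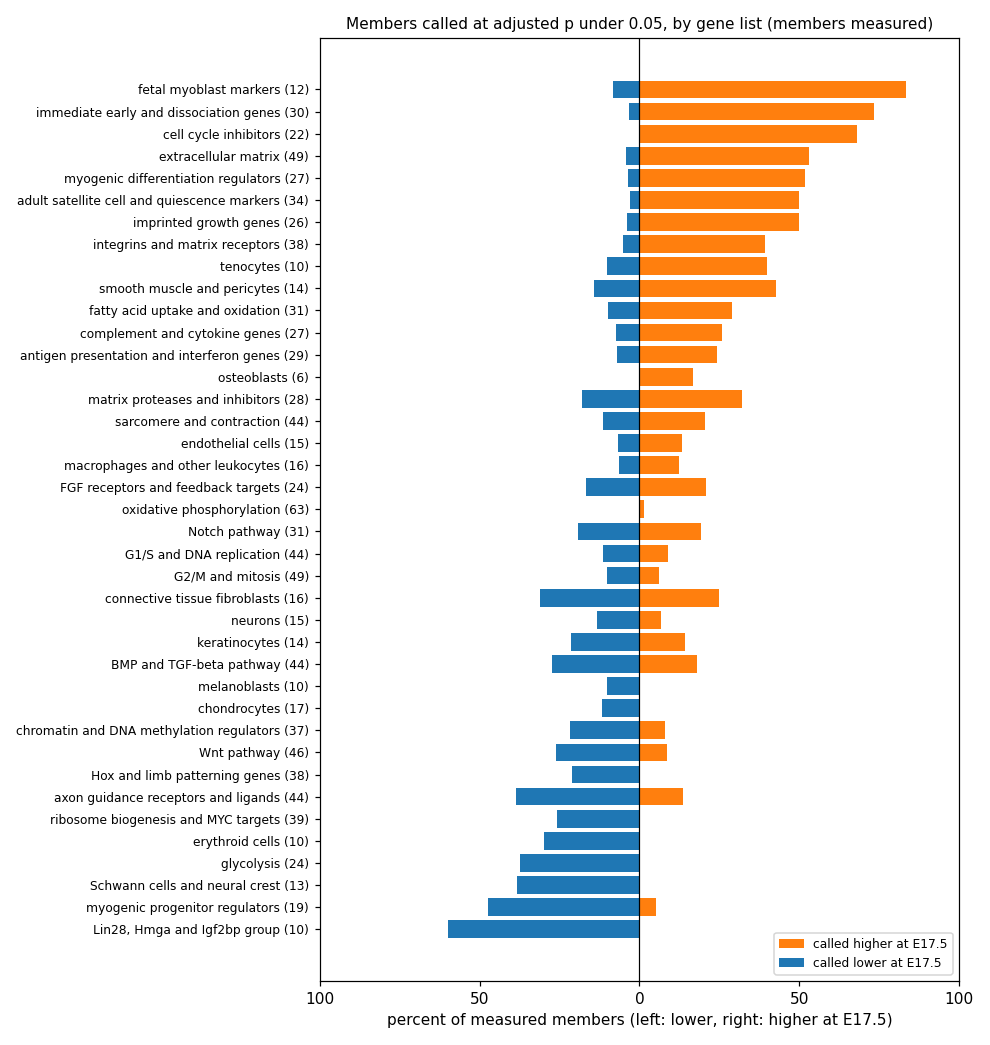
Share of each gene list's measured members (number in brackets) called higher (orange, right) or lower (blue, left) at E17.5 at an adjusted p under 0.05 in limma, with lists ordered by the difference of the shares. Fetal myoblast markers (10 of 12 higher) and immediate early genes (22 of 30 higher) stand at the top, and the Lin28, Hmga and Igf2bp group (6 of 10 lower) and muscle progenitor regulators (9 of 19 lower) at the bottom.

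Markers of 12 other cell types were examined, because a sort for GFP can carry over neighbouring cells. Connective tissue fibroblast genes moved apart: of 16 members 4 rose, 5 fell and 7 were not called (6 and 6 adjusted over the list alone, averaged count 3 and 3, without 1 array 3 to 7 and 2 to 5, camera adjusted p = 0.533). The 7 rises came without E12.5 replicate B. Dpt and Ogn (2.11) rose, and the limb mesenchyme factor gene Twist1 fell by 4.71. With array weights the list was called higher (median 0.58, adjusted p = 0.0193). Of 17 chondrocyte genes none rose, 2 fell and 15 were not called, with the same counts adjusted over the list alone and averaged (without 1 array 0 to 1 and 1 to 2, camera adjusted p = 0.404). One of those falls, that of Col9a1 (-4.02), was lost without any one of the E12.5 arrays. These genes also varied within an age. Over the 20 fibroblast and chondrocyte members with a mean of at least 6, the median was 1.4 higher in E12.5 replicate B than in the mean of A and C, and 1.09 higher in the mean of E17.5 A and B than in C.

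**Figure D3:**
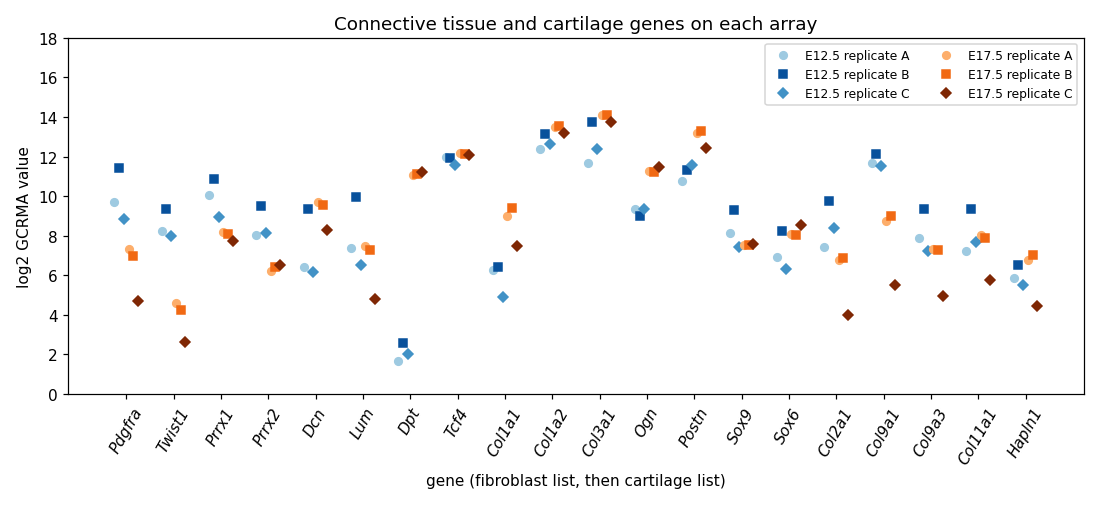
Log2 GCRMA values on each of the 6 arrays for the 20 fibroblast and cartilage genes with a mean of at least 6, each symbol being 1 array (blue E12.5, orange to brown E17.5). In 19 of the 20 genes E12.5 replicate B lay above the mean of replicates A and C, and in 15 of the 20 the mean of E17.5 replicates A and B lay above replicate C.

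Of 10 tenocyte genes 4 rose, including Thbs4 (3.40), 1 fell (Mkx, -3.41) and 5 were not called (5 and 1 adjusted over the list alone, averaged count 2 and 1, without 1 array 2 to 4 and 1). The camera call (adjusted p = 0.00952) was lost with an estimated correlation (adjusted p = 0.428), without E12.5 replicate A (adjusted p = 0.0508) and over genes with a mean of at least 6 (adjusted p = 0.127). Without members that another list also holds the list's median was -0.20 (adjusted p = 0.971). Of 14 smooth muscle and pericyte genes 6 rose, 2 fell and 6 were not called, with the same counts adjusted over the list alone and an averaged count of 4 and 1 (without 1 array 4 to 6 and 1 to 3). Tagln and Rgs5 rose by 5.22 and 3.89, and Pdgfrb fell by 3.84. The camera call (adjusted p = 0.026) was lost with an estimated correlation (adjusted p = 0.154) or one of 0.05 (adjusted p = 0.078), over genes with a mean of at least 6 (adjusted p = 0.125), without E12.5 replicate A (adjusted p = 0.0546) and without shared members (adjusted p = 0.0722). Acta2, the other call of that list that was lower, had probe sets called in opposite directions. Schwann cell and neural crest genes were lower: none of 13 rose, 5 fell and 8 were not called, with the same counts adjusted over the list alone and an averaged count of 0 and 4 (without 1 array 0 and 3 to 5). The neurotrophin receptor gene Ngfr fell by 3.65 and Erbb3 fell by 2.80. The list's median difference was -0.54, and 8 members had a mean signal under 4. That median ran from -1.05 without E12.5 replicate C to -0.045 without E12.5 replicate B. Camera called the list lower in both fits (adjusted p = 0.000254 and 0.0142). The list was lower by camera (adjusted p = 0.00563; adjusted p = 0.128 with an estimated correlation; adjusted p = 0.181 with array weights).

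The other 7 cell type lists were not called by camera, with adjusted p between 0.114 for keratinocytes and 0.773 for macrophages and other leukocytes. Without E12.5 replicate C, keratinocyte genes (median -1.0, adjusted p = 0.00846) and erythroid genes (-0.0075, adjusted p = 0.0219) were called lower, the second also over members with a mean of at least 4 (-4.11, adjusted p = 0.019). Endothelial genes had a median of -0.35, which ran from -0.57 without E12.5 replicate C to -0.017 without E12.5 replicate B and was -0.21 without E17.5 replicate C. Over genes with a mean of at least 6 they were called higher (1.57, adjusted p = 0.0328). Of 10 erythroid genes 3 embryonic globins fell and 7 were not called, and of the 3 the fall of Hbb-y was called in the averaged fit. Of 15 endothelial genes 2 rose, including the angiopoietin receptor gene Tek (4.88), and 1 fell (Erg, -2.96). Of 16 leukocyte genes 2 rose, including Cd68 (2.99), and 1 fell. Of 15 neuronal genes 1 rose and 2 fell, none of which was called in the averaged fit. Of 14 keratinocyte genes 2 rose, including Krt10 (2.14), and 3 fell, including Epcam (-4.10). Of 10 melanoblast genes 1 fell (Kit, -2.61), and of 6 osteoblast genes 1 rose (Dmp1, 4.89). Adjusted over the list alone the counts were 0 and 3 for erythroid, 2 and 1 for endothelial, 2 and 1 for leukocyte, 1 and 4 for neuronal, 2 and 4 for keratinocyte, 0 and 1 for melanoblast and 1 and 0 for osteoblast genes. The averaged counts were 1 and 1 for endothelial, 1 and 0 for leukocyte, 1 and 3 for keratinocyte, 0 and 1 for melanoblast and 1 and 0 for osteoblast genes. Without 1 array they were 0 and 1 to 4 for erythroid, 1 to 2 and 1 to 2 for endothelial, 1 to 2 and 0 to 1 for leukocyte, 0 to 1 and 0 to 3 for neuronal and 1 to 2 and 3 to 4 for keratinocyte genes.

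Over all 39 lists, 13 were higher and 8 lower by camera with a preset correlation of 0.01. With an estimated correlation 3 were higher, namely satellite cell and quiescence markers, cell cycle inhibitors and integrins, and none was lower at an adjusted p under 0.05 (4 were lower at an unadjusted p under 0.05). That test gave larger p-values also where the estimate lay under 0.01. For Wnt genes (estimate -0.0036) the unadjusted camera p went from 0.00206 to 0.0207. A call lost with it is therefore not by itself a sign of correlated members. By fry, which tests a list's own members and not against other genes, 17 lists were higher and 11 lower. Each of the 9 other divisions of the 6 arrays gave between 12 and 25 camera calls at the preset correlation, against 21 for the ages. Those divisions mix the ages unevenly and keep part of the age difference. They therefore do not show how many calls arise without age.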

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

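The averaging of E17.5 replicates A and B and the lists without shared members were chosen after the data were seen. The counts kept within 1.5 times of the reported ones under other variance priors, other probe set choices, centring, quantile normalization and a floor at 4. Array weights (4.80 for E12.5 C, 4.98 and 3.24 for E17.5 A and B, 0.140 to 0.386 for the others) gave 3204 genes higher and 5220 lower and 4 lists lower. These counts lean on E17.5 A and B, which may not be independent. A threshold of 0.01 gave 841 higher, 701 lower and 572 lower by at least 2-fold. The averaged fit gave 825 lower. A mean of at least 6 left 611 genes lower by at least 2-fold and 4 lists lower, with fewer genes tested, and 7 lists lost their call. The estimated correlation gave 3 lists higher and 0 lower. Leaving out 1 array at a time gave 970 to 1553 higher, 771 to 1776 lower, 834 to 1064 and 616 to 970 by at least 2-fold, 11 to 14 lists higher and 7 to 10 lower.

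The replicate letter as a block gave 1014 lower and 1091 higher. Deviations of arrays of the same letter correlated at -0.38 (A), 0.25 (B) and -0.07 (C) across genes, so the letters do not pair the arrays. Between other letters the correlations ran from -0.34 (E12.5 B with E17.5 C) to 0.37 (E12.5 A with E17.5 C), with 0.36 for E12.5 B with E17.5 A. No list call changed under the block.

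Endothelial genes with a mean of at least 6 had a median of 1.57 (camera adjusted p = 0.0328), and tenocyte genes without shared members one of -0.20 (adjusted p = 0.971). Without probe sets that can match several transcripts, Slc2a3 was at 0.01, Angptl4 at 0.40, Laptm5 at 0.047 and Acta2 at 1.16, and with the mean of probe sets Acta2 was at 0.17. The causes of these changes were not tested. Of 194 named genes 42 lost their call in the averaged fit, 41 with the floor, 26 with the block and 20 to 47 without 1 array. In those fits no gene changed sign that was called there or in the main fit. Sign changes of genes without a call were not counted. The planned 3' to 5' control alternatives were not run. Signal over background limits the genes with a mean under 4.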

Other observations

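The tests on connective tissue genes, on the scaling of immediate early genes and on handling tied to age were chosen after the result was seen, as were the genes named in the next 2 paragraphs.

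Several caveolar coat genes were higher at E17.5, in a list drawn up because they were seen to rise, so no set test applies. Cavin2 rose from 6.98 to 13.15 (difference 6.17, SE 0.15, adjusted p = 2.32e-05 by limma, higher in 3 of 3 arrays), Cavin1 by 5.52, Cav2 by 5.34, Cavin3 by 5.02 and Cav1 by 4.72, and the muscle caveolin gene Cav3 by 2.90. Of the 9 measured members of a list of 10, 8 rose, none fell, and Cavin4, near the lower end of the scale, was not called. Of these, 1 (Cav1) was also in the satellite cell list. Which cells carried this rise was not tested. Of the smooth muscle, pericyte and endothelial markers, Tagln (5.22), Rgs5 (3.89) and Tek (4.88) rose too, while Pdgfrb (-3.84) and Erg (-2.96) fell. Cav1, Cavin1 and Cavin3 were highest at E12.5 in replicate B, where fibroblast genes also stood higher (8.08, 5.74 and 5.31). So were Cav2, Cav3 and Ehd2 (4.39, 3.36 and 6.54), but not Cavin2 and Pacsin3. At E17.5 Cavin1 and Cavin3 were highest in replicate C (10.55 and 9.26), where fibroblast genes stood lower. Cav1, Cav2, Cav3, Ehd2 and Pacsin3 were lowest there (11.90, 8.96, 5.90, 8.20 and 7.79), and Cavin2 lay between A and B.

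The fixed BMP and TGF-beta list was not called (8 of 44 higher, 12 lower, camera adjusted p = 0.362), and single genes within it went both ways. Id2 fell from 12.66 to 10.66 and Id3 from 12.28 to 10.16 (adjusted p = 0.000314 and 0.00011), Smad6 fell by 2.21, and Id1 and Smad7 were at -1.93 and -1.28, with calls lost in several fits. That of Id1 was lost in the averaged fit, with the floor, the replicate block, no variance trend, all probe sets or a further quantile normalization, and without E12.5 B, E12.5 C or E17.5 B (adjusted p 0.0564 to 0.119), and that of Smad7 in the averaged fit and without E12.5 C, E17.5 A or E17.5 B (0.0551 to 0.0615). Bmp6 and Bmp4 rose by 5.51 and 3.07, the second without a call with the floor at 4 (adjusted p = 0.0597), without E12.5 replicate A (0.0511) or without E17.5 replicate C (0.0566). The myomaker and myomixer genes Mymk and Mymx, which drive myoblast fusion, rose by 2.99 and 3.06, and Meg3, which shares its imprinted cluster with Dlk1, Rian and Mirg, rose by 2.31.

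E17.5 replicates A and B differed less than other arrays of one age. Over genes with a mean under 4 the SD of their difference was 0.633 times the smallest among the other 5 pairs, between the bounds set beforehand for and against a single hybridised array scanned more than once, so that reading stays open. The smallest of the other SDs there (0.207) was that of E12.5 A and C, which also held the same value in 8666 probe sets against 8939 for E17.5 A and B, but in 221 against 516 with a mean of at least 6. Xist and the measured Y-linked genes differed by at most 0.04 between E17.5 A and B, against 0.57 to 2.57 in the other same-age pairs. Separate pools processed side by side would need a like mix of sexes to give this. That favours 1 cell or RNA sample behind both arrays. No test was set beforehand for either reading, and neither is excluded. If the arrays share a sample, the averaged counts of 1021 higher and 825 lower are the ones to use.

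Fibroblast and cartilage genes varied together between arrays of one age, with a median 1.4 higher in E12.5 B than in A and C, and 1.09 higher in E17.5 A and B than in C. A share of connective tissue cells that differs between preparations had no test apart from this pattern and stays open; the collagen genes Col1a2 and Col3a1 stood at 12.36 to 13.53 and 11.70 to 14.09 on the arrays, 6 of the 20 genes are also in another list, and the sort for GFP should remove such cells. A smaller share of like cells at E17.5 would not raise the 2 genes Ogn and Postn, which rose with and without any 1 array, among 9 fibroblast genes with an E12.5 mean of at least 8 of which 4, Pdgfra, Twist1, Prrx1 and Prrx2, fell. Ogn did not follow the within-age pattern and Postn did so in part (Ogn at 9.0 in E12.5 B against 9.36 and 9.33, and 11.48 in E17.5 C, its highest; Postn at 11.30 in E12.5 B against 10.79 and 11.59, but at 12.41 in E17.5 C against 13.19 and 13.27) and Postn is in another list, so they say nothing of the rest. For the genes that fell, of which Pdgfra and Prrx1 each lost their call in 4 of the 6 fits without 1 array, a smaller share, and a change of expression with age, stay open.

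Immediate early genes were higher at E17.5. Array scaling or expression level is argued against by the list's median of 2.77, at percentile 100 among matched random lists with an upper bound of 0.16. A handling response varying between preparations at either age was tested on the E12.5 arrays only. Their list medians (7.81 to 8.05) had a range 0.105 times the difference between the ages (2.29). That argues against such variation among the E12.5 arrays. It cannot decide the question for E17.5, or if the arrays of one age were prepared together. A handling response tied to the age of the tissue and a difference in the tissue itself cannot be told apart, since no handling control was analysed here: 26 of 30 members had all E17.5 arrays above all E12.5 arrays.

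Of the 10 ways to divide the 6 arrays into 3 and 3, 1 gave as many called genes as the ages, with 3080 called genes and 1956 by at least 2-fold against 0 and 0 as the highest of the others. For lists 3 of the 10 gave as many calls, 21 for the ages and 25 as the highest of the others, of which each gave at least 12. Part of the age difference remains in those divisions, so their counts do not show how many list calls arise without age. The division with 25 sets E12.5 A, E12.5 C and E17.5 C against E12.5 B, E17.5 A and E17.5 B. By limma it had 0 called genes but 4335 at an unadjusted p under 0.05 (5165 for the ages), which points to a structure of the arrays other than age. With 10 divisions the share cannot go under 0.1.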
